A study of Mus musculus with 18 samples.

How the data were processed

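RNA was sequenced from FACS-sorted bone marrow neutrophils of 10-week-old WT mice and mice labelled CIS-/-, unstimulated or after 4 h or 24 h with 100 ng/mL GM-CSF, in 18 libraries. The samples fall into 6 groups of 3, per the labels. The labels' treatment protocol gives 42 h where the titles and the extraction protocol give 24 h; 24 h was used. Per the labels' protocols, libraries came from a strand-specific kit and were sequenced on an Illumina NextSeq. The deposited values are raw read counts per Ensembl gene, which the authors made with Trimmomatic, STAR and featureCounts on the mm10 build, per the submitters' processing notes. Versions, the strand setting of the counting and the annotation release are not given in the sources used here. The counts were whole numbers whose totals differed between libraries. Totals ran from 12170524 to 22539858 per library.

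Of 53379 gene IDs, 53274 had a name in GENCODE mouse release M21, which also gave coordinates on GRCm38, the assembly of mm10; the 105 others held 0.0238% of the counts. No count was found for 29393 IDs in any library. No pair of replicates was a duplicate: the chi-square per degree of freedom between 18 pairs of replicates lay between 1.285 and 8.461, the highest for replicates 1 and 3 labelled CIS-/- at 24 h.

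Genes were tested in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr by group, which left 11569 genes and 99.928% of the counts. Libraries were scaled with TMM factors and 1 quasi-likelihood model of the 6 groups was fitted to the 18 libraries with robust dispersion. The common biological coefficient of variation was 3.3%, with 12 residual degrees of freedom and a median of 45.5 prior degrees of freedom. Contrasts between groups, the mean genotype difference and the genotype-by-time interactions were tested two-sided with glmQLFTest, and Benjamini-Hochberg adjusted p under 0.05 counted as called. The 11 comparisons, 30 gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. Each adjusted p for a gene is from this edgeR quasi-likelihood test.

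By that rule Cish is given first. Then come the 8 genes with the largest positive and the 8 with the largest negative log2 fold change among called genes with at least 10 CPM in a compared group, groups that do not overlap (not asked of interactions and means) and a name other than a clone or pseudogene. For each list, the 4 members with the smallest adjusted p and at least 1 CPM follow. Names were taken from these in rank order as room allowed. CPM use TMM-scaled library sizes. A gene with no count in a group is given as a bound against a floor of 3 counts over the group, and 1 with 1 to 3 counts as a ratio with a 95% counting interval.

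The lists had 706 entries, of which 704 matched 1 gene name, 1 matched a name with 2 IDs (the ID with more counts was used) and 1 was not matched. They cover SOCS family, STAT5-associated response, GM-CSF receptor and JAK-STAT, cytokines and chemokines, MHC class I and II, granules, receptors, NADPH oxidase, apoptosis, metabolism, cell cycle, interferon, NF-kB, immediate-early genes, protein stress, ribosome biogenesis and markers of other cells. Lists share members: several cytokine genes are also NF-kB genes, and neutrophils express many listed monocyte markers. List p-values are from camera in limma 3.58.1 with a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists of a comparison; camera with an estimated correlation and fry, which does not compare a list with other genes, were run beside it. Members were also counted with p adjusted over the list alone. Replacing fitted values by bounds for members at 0 in a group moved no list median by more than 0.1 of the 232 compared.

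The pipeline was tested on simulated counts with 200 changed genes. For unstimulated libraries labelled CIS-/- against WT (11438 genes), 44% of genes changed 1.25-fold, 62% of those changed 1.5-fold, 82% at 2-fold and 94% at 3-fold were recovered, and 4.7% of the calls were unchanged genes. For the 4 h genotype comparison (11432 genes) 52, 60, 74 and 94% were recovered with 9.1% unchanged genes among the calls, and for the 24 h genotype comparison (11336 genes) 56, 72, 80 and 92% with 9.6%. For the 24 h interaction (11369 genes) 44, 60, 70 and 66% were recovered, the last at 3-fold, with 5.5% unchanged genes among the calls.

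The alternatives fixed in advance were RLE factors, DESeq2 1.42.0, limma-voom, no low-count filter, a strict filter of 50 counts in 3 libraries, a fit of the compared groups only, a replicate block, each library left out, a non-robust prior and an absolute log2 fold change of at least 1. Library sizes without TMM factors, the genotype comparisons without a window of 29 Mb around Cish on chromosome 9, and the SOCS family list without Cish were added after seeing the data. Genes that overlap others were not set apart, and alignments were not used here. No batch or date is given in the labels. Some results for single genes are not reported here.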

Results

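RNA was sequenced from neutrophils sorted from the bone marrow of 10-week-old wild-type (WT) mice and mice labelled CIS-/-, a knockout of Cish per the labels, the gene of the cytokine-signalling inhibitor CIS. The series asks how CIS limits the action of GM-CSF, a growth factor of myeloid cells that drives joint inflammation. Cells were lysed after sorting (unstimulated) or cultured for 4 h or 24 h with 100 ng/mL GM-CSF, giving 6 groups of 3 libraries. Each library is an entry of its own in the labels, which do not say whether replicates are separate mice, so p-values measure only the spread between these 18 libraries. No library came from cells cultured without GM-CSF, so culture time and GM-CSF changed together.

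The deposited table held counts for 53379 genes. Total counts of the WT libraries were 15749168, 14378755 and 17944849 unstimulated, 14267588, 15967505 and 13679004 at 4 h, and 16724733, 22455449 and 15818310 at 24 h. Those of the libraries labelled CIS-/- were 16362343, 15640535 and 15339469 unstimulated, 12612313, 19164043 and 12841160 at 4 h, and 14600432, 12170524 and 22539858 at 24 h. Between 15198 and 16744 genes had a count in a library, and 11569 genes entered the tests. The 1st principal component held 61.9% of the variance and the 2nd 20.3%. Values below are mean CPM (counts scaled to a common library size) ± SD over the 3 libraries of a group, log2 fold changes are given ± SE, and changes are relative to the bulk of all genes.

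Cish (ENSMUSG00000032578.7), the targeted gene, was examined first in every library. In the WT libraries Cish stood at 6.48, 6.52 and 6.5 CPM unstimulated, at 1160, 1140 and 1150 CPM at 4 h, and at 1070, 1060 and 1060 CPM at 24 h. In the libraries labelled CIS-/- Cish stood at 18.3, 20 and 17.9 CPM unstimulated, at 243, 240 and 237 CPM at 4 h, and at 238, 243 and 233 CPM at 24 h. After GM-CSF the libraries labelled CIS-/- thus held less Cish than WT, with log2 fold changes of -2.26 ± 0.03 at 4 h (edgeR adjusted p = 1.85e-52) and -2.16 ± 0.03 at 24 h (edgeR adjusted p = 1.81e-53). Before GM-CSF they held more Cish, with a log2 fold change of 1.52 ± 0.08 (adjusted p = 4.72e-25), which goes against their label. They are therefore called libraries labelled CIS-/- here. In a window of 29 Mb around Cish, 12 genes differed in 1 direction at all 3 conditions and at least 1.5-fold. Among them were Col6a4 (log2 fold changes of 6.82, 7.43 and 3.53) and Rpl29 (-2.13, -2.26 and -2.89), unstimulated, at 4 h and at 24 h. A swap of genotypes among the unstimulated libraries alone would turn their sign there. These genes thus argue against it, although they were picked for keeping 1 direction. The labels do not say which part of Cish was deleted, and the counts cover the whole gene, so reads from what is left of it count too. Gm17040, a transcript of unknown function chosen after its values were seen, lies on the opposite strand of chromosome 9 (107292435 to 107297192, mm10) and overlaps the start of Cish (107296026 to 107302784). It was counted at 3.07 ± 0.5 CPM in WT and 33.5 ± 0.14 CPM in libraries labelled CIS-/- at 4 h. The strand setting of the counting is not given in the sources used here, so the level of either gene within the overlap is uncertain.

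**Figure D1:**
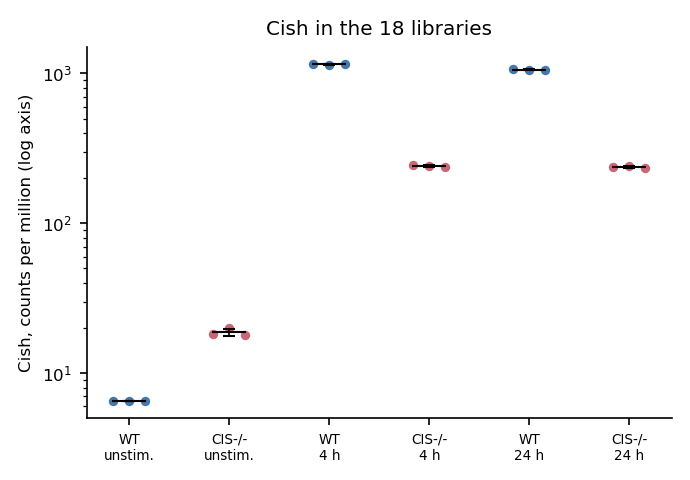
Cish in each of the 18 libraries, in CPM on a log axis; points are libraries (blue WT, red labelled CIS-/-), and black lines mark the mean and SD of 3. WT libraries rose from 6.5 to 1150 CPM at 4 h, and the libraries labelled CIS-/- from 18.7 to 240 CPM.

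The response of WT neutrophils to 4 h in GM-CSF was a broad change of program. Cish itself, a target of the GM-CSF receptor's STAT5 pathway, rose by a log2 fold change of 7.46 ± 0.05. All 36 tested interferon-stimulated genes rose, among them Oasl2, an antiviral gene, from 167 ± 3.2 to 3100 ± 85 CPM, and Gbp2, a guanylate-binding protein, from 31.7 ± 1.1 to 1170 ± 36 CPM (camera adjusted p = 2.92e-42). Fcgr2b, the inhibitory IgG receptor, rose from 38.6 ± 1.2 to 2380 ± 73 CPM. The immediate-early genes Fos and Fosb, high in freshly sorted cells, fell, Fos from 1390 ± 7.8 to 66.8 ± 1.3 CPM. In all, 4404 genes rose and 4422 fell, and 4004 of these changed at least 2-fold.

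Among the single genes with the largest rises after 4 h, C3ar1, the receptor of complement C3a, had no count in unstimulated WT cells and reached 12.1 ± 1.4 CPM, at least 202-fold higher against a floor of 3 counts over the group. Hbegf, an epidermal growth factor family member, had 3 counts before and was 1530 times as high after (95% counting interval 523 to 7420). Rab15, a trafficking GTPase, rose by 9.49 ± 0.10 and F10, coagulation factor X, by 8.83 ± 0.09 on the log2 scale. Among the largest falls were Ptgs2, the prostaglandin-making enzyme COX-2, which went from 185 ± 3.5 to 8.29 ± 1.3 CPM, and Lct, with a log2 fold change of -5.05 ± 0.21. Intervals and floors cover counting error only.

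By list at 4 h, 6 of 8 SOCS family genes rose, Cish among them (adjusted p = 5.31e-06, and 0.021 without Cish, an alternative added after seeing the data), including Socs1 by 4.27 ± 0.06. Of 21 STAT5-associated genes, 14 rose and 6 fell (adjusted p = 2.75e-05), led by the survival gene Bcl2l1, which rose by 3.39 ± 0.04, and the kinase gene Pim1, by 1.86 ± 0.03. The GM-CSF receptor and JAK-STAT genes moved both ways, 14 up and 13 down of 30 (adjusted p = 0.137); Csf2rb, the receptor's shared beta chain, rose from 620 ± 4.8 to 1840 ± 29 CPM and Jak2 from 115 ± 1.4 to 906 ± 12 CPM. MHC class II and costimulation genes rose in 11 of 14 and fell in 2 (adjusted p = 1.36e-07), led by Cd274, the checkpoint ligand PD-L1, and the protease gene Ctss. MHC class I genes rose in 13 of 18 and fell in 2 (adjusted p = 1.42e-05), with their transactivator Nlrc5 up by 5.65 ± 0.06. Cytokines and chemokines rose in 17 of 25 and fell in 4 (adjusted p = 9.2e-05, but 0.133 as the adjusted p with an estimated correlation). Spp1 and Csf1 rose, while Il1b fell from 981 ± 7.1 to 202 ± 5.2 CPM. The immediate-early list fell in 16 of 26 and rose in 7 (adjusted p = 5.64e-06), with Junb at -3.03 ± 0.04. NF-kB response genes rose in 20 of 29 and fell in 6 (adjusted p = 0.0442, and 0.176 with an estimated correlation), a call that was lost without WT unstimulated replicate 1 (adjusted p = 0.056) or replicate 3 (adjusted p = 0.0535).

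At 4 h camera called the specific granule and NADPH oxidase lists lower, calls that were lost with an estimated correlation. Specific and gelatinase granule genes fell in 18 of 30 and rose in 6 (adjusted p = 2.75e-05, and 0.309 as the adjusted p with an estimated correlation), with Hp, haptoglobin, at -1.51 ± 0.04. Of the NADPH oxidase genes, which make the respiratory burst, 6 of 8 fell (adjusted p = 0.0166, and 0.261 with an estimated correlation); Cybb went from 1760 ± 42 to 635 ± 14 CPM. The 12 azurophil granule genes split 4 and 4 (adjusted p = 0.311). Pro-apoptotic genes rose in 11 of 18 and fell in 6 (adjusted p = 0.0171, a call lost with limma-voom, adjusted p = 0.0761), Bcl2l11 by 3.34 ± 0.05 and Bax by 3.46 ± 0.08, and anti-apoptotic genes in 10 of 16 with 4 lower (adjusted p = 0.0543). The unfolded-protein and amino-acid stress list rose in 16 of 27 and fell in 11 (adjusted p = 6.83e-05), with Xbp1 from 71.3 ± 1.8 to 1520 ± 14 CPM. Hypoxia genes rose in 7 and fell in 8 of 15; camera called the list higher (adjusted p = 0.0158) although its median was -0.22 and its mean 0.29, a call lost with limma-voom (adjusted p = 0.697); Egln3 rose by 4.95 ± 0.04 and Hmox1 by 3.40 ± 0.04. Migration and activation receptors rose in 26 of 41 and fell in 15 (adjusted p = 6.83e-05, and 0.135 with an estimated correlation). Glycolysis (7 up, 14 down of 21, adjusted p = 0.167), oxidative phosphorylation (4 up, 30 down of 40, adjusted p = 0.0543), ribosome biogenesis (13 up, 6 down of 34, adjusted p = 0.765), cholesterol synthesis (10 up, 10 down of 24, adjusted p = 0.862) and the cell cycle (3 up, 26 down of 37, adjusted p = 0.0625) did not pass the list test. Adjusted over the list alone, 18 in place of 17 cytokine genes were called higher and 2 in place of 3 eosinophil and basophil genes lower, and every other count of this comparison was unchanged.

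After 24 h in WT neutrophils, specific and gelatinase granule genes had fallen and most interferon genes had gone below their starting level. Ltf, lactoferrin, fell from 11400 ± 200 to 261 ± 4 CPM, and 27 of 30 specific and gelatinase granule genes fell while 2 rose (adjusted p = 7.4e-45); the 12 azurophil granule genes split, 5 up and 6 down (adjusted p = 0.37). Cell cycle genes fell in 33 of 37 and rose in 1, Top2a from 57.8 ± 0.25 to 6.05 ± 1.1 CPM (adjusted p = 1.47e-07, and 0.0626 with an estimated correlation). Cholesterol synthesis and uptake genes rose in 22 of 24 and fell in 1 (adjusted p = 2.48e-08), Cyp51 from 9.78 ± 0.5 to 63.2 ± 2.3 CPM. Of 36 interferon-stimulated genes, 33 were below the unstimulated level and 2 above it (adjusted p = 9.13e-13); Oas3 had a log2 fold change of -3.47 ± 0.04, while Oasl2 was still higher by 2.69 ± 0.03. Cish stayed high, by 7.35 ± 0.05.

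In this 24 h comparison 4707 genes rose and 4361 fell. With library sizes in place of TMM factors, an alternative chosen after seeing the data, 6352 were higher and 3164 lower and the median of all genes was 0.36. C3ar1 was at least 689-fold and Car4, a carbonic anhydrase, at least 503-fold above a floor of 3 counts. Chil5 was among the largest falls, with a log2 fold change of -8.33 ± 0.16. All 8 NADPH oxidase genes fell (adjusted p = 4.55e-05, and 0.0725 with an estimated correlation), Cybb from 1760 ± 42 to 117 ± 4.3 CPM. Immediate-early genes fell in 19 of 26 and rose in 5 (adjusted p = 1.13e-07) and SOCS genes rose in 5 of 8 and fell in 1 (adjusted p = 0.000425, and 0.0608 with limma-voom and 0.281 without Cish). Cytokine genes rose in 14 of 25 and fell in 7 (adjusted p = 0.0242, and 0.344 with an estimated correlation); Ccl6 went from 1460 ± 24 to 6150 ± 170 CPM and Osm, oncostatin M, from 424 ± 5 to 63.9 ± 1 CPM. The unfolded-protein list rose in 19 of 27 and fell in 7 (adjusted p = 0.0029, and 0.101 with an estimated correlation). MHC class II and costimulation genes rose in 7 of 14 and fell in 3 (adjusted p = 0.000445, and 0.0917 with an estimated correlation). Their median of 0.65 turned its sign without WT unstimulated replicate 1. Glycolysis genes fell in 13 of 21 and rose in 6 (adjusted p = 0.000265, and 0.182 with an estimated correlation), with Ldha at -1.92 ± 0.04. The STAT5-associated list was split, 11 up and 10 down (adjusted p = 0.915).

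Tested directly, 24 h against 4 h in WT cells, the interferon-stimulated genes fell in 36 of 36 (adjusted p = 9.1e-136). Gbp2 dropped from 1170 ± 36 to 4.25 ± 0.23 CPM and Rsad2, viperin, from 499 ± 8.3 to 5.57 ± 0.19 CPM. MHC class I genes fell in 13 of 18 and rose in 4 (adjusted p = 3.66e-11) and STAT5-associated genes in 17 of 21 with 1 higher (adjusted p = 4.22e-07). Cholesterol genes rose in 23 of 24 (adjusted p = 1.11e-10), Insig1 by 2.62 ± 0.07. Spp1, osteopontin, fell back from 115 ± 1.4 to 5.57 ± 0.67 CPM. Tmcc3 rose by 5.05 ± 0.11. Cish was lower at 24 h by a log2 fold change of -0.12 ± 0.03, a sign that turned with library sizes alone. In all 4128 genes rose and 4586 fell; with library sizes alone 6763 were higher and 2506 lower, with a median of all genes of 0.448.

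Cells labelled CIS-/- changed much as WT cells did in the first 4 h, measured against the unstimulated libraries whose Cish goes against the label, as is the 24 h change. Gbp2 went from 32.9 ± 1.9 to 1040 ± 19 CPM and Oasl2 from 157 ± 1.8 to 3080 ± 53 CPM, and interferon-stimulated genes rose in 36 of 36 (adjusted p = 8.99e-31). Socs1 rose by 3.78 ± 0.05, within a SOCS list of 4 up and 1 down of 8 (adjusted p = 0.00245), a call lost in a fit of the compared groups only (adjusted p = 0.0698), with limma-voom (adjusted p = 0.12) and without Cish (adjusted p = 0.0881). Immediate-early genes fell in 18 of 26 and rose in 6 (adjusted p = 1.75e-10), with Fosb at -5.20 ± 0.14. Dab2, an endocytic adaptor, was at least 560-fold above a floor of 3 counts. Of 8907 genes called, 4381 rose and 4526 fell; 3904 rose and 3931 fell in both genotypes, where independent lists would share 1668 and 1730, and 97 went opposite ways. Across genes, which are not independent replicates, the 4 h log2 fold changes of the genotypes had r = 0.938.

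After 24 h the libraries labelled CIS-/- showed an inflammatory program beside lower specific and gelatinase granule genes. Csf1, the macrophage growth factor M-CSF, rose from 54.6 ± 2.2 to 5400 ± 150 CPM. Il1rn, the interleukin-1 receptor antagonist, rose from 320 ± 2.8 to 7210 ± 180 CPM, and Tnf from 27.7 ± 0.82 to 560 ± 31 CPM. Cytokine genes rose in 20 of 25 and fell in 5 (adjusted p = 1.38e-18) and NF-kB response genes in 26 of 29 with 3 lower (adjusted p = 1.16e-26). Dab2 was at least 11000-fold, Car4 at least 8340-fold and Il23a, the interleukin-23 subunit p19, at least 640-fold above a floor of 3 counts. Specific and gelatinase granule genes fell in 26 of 30 and rose in 4 (adjusted p = 1.26e-21), with Lrg1 at -6.22 ± 0.05, and interferon-stimulated genes fell in 33 of 36 and rose in 3 (adjusted p = 4.1e-06, and 0.118 with an estimated correlation). Cholesterol genes rose in 22 of 24 and fell in 2 (adjusted p = 7.5e-11). Of 9727 genes called, 4865 rose and 4862 fell. Across genes the 24 h changes of the genotypes had r = 0.814, and 1158 called genes went opposite ways.

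Freshly sorted cells already differed between genotypes. The libraries labelled CIS-/- held more Socs3, an inhibitor of STAT3 signalling, at 1800 ± 19 against 678 ± 4 CPM, and more Cd14, the endotoxin co-receptor, at 120 ± 1.6 against 39.2 ± 1 CPM. NF-kB response genes were higher in 21 of 29 and lower in 2 (adjusted p = 1.67e-45), among them Nfkbia by 0.80 ± 0.04 and Tnfaip3 by 0.86 ± 0.05. Immediate-early genes were higher in 23 of 26 and lower in 1 (adjusted p = 6.14e-37), Atf3 by 1.20 ± 0.05 and Egr1 by 0.99 ± 0.04. These directions rest on unstimulated libraries in which Cish goes against the label, while 12 genes near Cish kept 1 direction at all 3 conditions.

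Of 2578 genes called in unstimulated cells, 1489 were higher and 1089 lower in the libraries labelled CIS-/-, and 202 differed at least 2-fold. With library sizes alone 1168 were higher and 1660 lower. STAT5-associated genes were higher in 12 of 21 (adjusted p = 3.18e-21), Pim1 at 630 ± 5.2 against 380 ± 7.4 CPM, and SOCS genes in 3 of 8, Cish among them (adjusted p = 1.34e-11, and 6.59e-08 without Cish). Cytokine genes were higher in 13 of 25 and lower in 1 (adjusted p = 1.34e-11), Ccl4 by 2.14 ± 0.08 and Il1b by 0.60 ± 0.03. Hypoxia genes were higher in 8 of 15 (adjusted p = 0.00139). MHC class II and costimulation genes were higher in 6 of 14 (adjusted p = 8.95e-05), Cd80 and Ctsl among them. Migration receptors were higher in 13 of 41 and lower in 6 (adjusted p = 1.03e-06, and 0.0609 with an estimated correlation). Glycolysis (7 of 21 higher and 1 lower, adjusted p = 0.000119, and 0.138 with an estimated correlation), anti-apoptotic genes (6 of 16 higher and 1 lower, adjusted p = 8e-04, and 0.0614) and cholesterol genes (8 of 24 lower and 3 higher, adjusted p = 0.012, and 0.0751) lost their call with an estimated correlation. Cell cycle genes were lower in 22 of 37 and higher in 3 (adjusted p = 2.28e-05), with Top2a at -0.52 ± 0.06, and interferon-stimulated genes in 14 of 36 with 1 higher (adjusted p = 0.00618). Erythroid markers moved with the genotype: 9 of 10 were higher (adjusted p = 2.5e-10), Hba-a1 at 24.6 ± 0.5 against 9.47 ± 0.47 CPM. Adjusted over the list alone, 22 NF-kB, 13 STAT5-associated and 8 MHC class II and costimulation genes were higher, and 23 cell cycle and 15 interferon-stimulated genes lower.

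After 4 h of GM-CSF, interferon-stimulated genes were lower in the libraries labelled CIS-/- than in WT, in 27 of 36 (adjusted p = 9.9e-38; 30 lower adjusted over the list alone), with Ifit3 at 23.2 ± 0.94 against 54.1 ± 2.5 CPM and Rsad2 at 297 ± 3.6 against 499 ± 8.3 CPM. NF-kB response genes were higher in 21 of 29 (adjusted p = 2.29e-21), by small amounts such as 0.43 ± 0.03 for Nfkb1. Socs3 was higher, at 1550 ± 11 against 990 ± 13 CPM. Of 21 STAT5-associated genes, 11 were higher and 3 lower (adjusted p = 1.04e-07), with Bcl6 up by 0.58 ± 0.04 and Il4ra by 0.29 ± 0.03.

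At this time 925 genes were higher and 1076 lower, and 126 differed at least 2-fold. Cell cycle genes were lower in 18 of 37 (adjusted p = 1.09e-07; 27 lower adjusted over the list alone). Erythroid markers were again higher, in 7 of 10 with 1 lower (adjusted p = 3.31e-09), Hbb-bs at 52 ± 10 against 15.1 ± 2 CPM. The SOCS list was called lower (adjusted p = 0.000287) with a mean of -0.13 and a median of 0.11, and camera gave the other direction under 3 of the alternatives fixed in advance; without Cish the list was called higher (adjusted p = 0.000758), as Cish was lower while Socs1 and Socs3 were higher. Eosinophil and basophil markers were called higher (adjusted p = 0.0185, and 0.265 with an estimated correlation) with 2 of 8 members higher and a median of -0.23. That median became 0.07 without WT 4 h replicate 2 and 0.01 with no low-count filter. Ccr3, the eotaxin receptor on chromosome 9, was one of the members higher, by 3.41 ± 0.17. Calls lost with an estimated correlation were those of migration receptors (20 higher, 5 lower, adjusted p = 9.34e-06, and 0.125), granule genes (3 higher, 12 lower of 30, adjusted p = 9.21e-05, and 0.344), cytokines (11 higher, 3 lower, adjusted p = 0.000262, and 0.166), anti-apoptotic genes (7 higher of 16, adjusted p = 0.00148, and 0.125), MHC class I (1 higher, 8 lower of 18, adjusted p = 0.0159, and 0.193), MHC class II (5 higher, 2 lower of 14, adjusted p = 0.0109, and 0.166), immediate-early genes (8 higher, 3 lower of 26, adjusted p = 0.0109, and 0.166) and NADPH oxidase (1 higher, 2 lower of 8, with a median of 0, adjusted p = 0.0278, and 0.299). The NADPH oxidase call was also lost without replicate 3 of the 4 h libraries labelled CIS-/- (adjusted p = 0.0917), and the eosinophil and basophil call without WT 4 h replicate 1 (adjusted p = 0.0516) or replicate 2 (adjusted p = 0.0511).

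At 24 h the genotypes had parted widely. Libraries labelled CIS-/- held neutrophil-attracting chemokines far above WT: Cxcl3 at 2810 ± 180 against 24.1 ± 2.4 CPM and Cxcl2 at 7480 ± 520 against 135 ± 8.7 CPM. Spp1, osteopontin, stood at 652 ± 33 against 5.57 ± 0.67 CPM, Csf1 at 5400 ± 150 against 198 ± 3.7 CPM, and Il1b at 1290 ± 75 against 177 ± 4.4 CPM. All 29 NF-kB response genes were higher (adjusted p = 2.7e-65), among them Ptgs2 by 4.73 ± 0.05 and Ccrl2 by 5.18 ± 0.04. Ccrl2 lies near Cish on chromosome 9 and was already higher by 2.52 in unstimulated cells and by 2.43 at 4 h. Lower genes included Cd101, an inhibitory surface protein, at 23.1 ± 0.58 against 575 ± 2.9 CPM, and Bmx, a Tec family kinase gene, at 1.18 ± 0.15 against 43.3 ± 1.1 CPM.

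**Figure D2:**
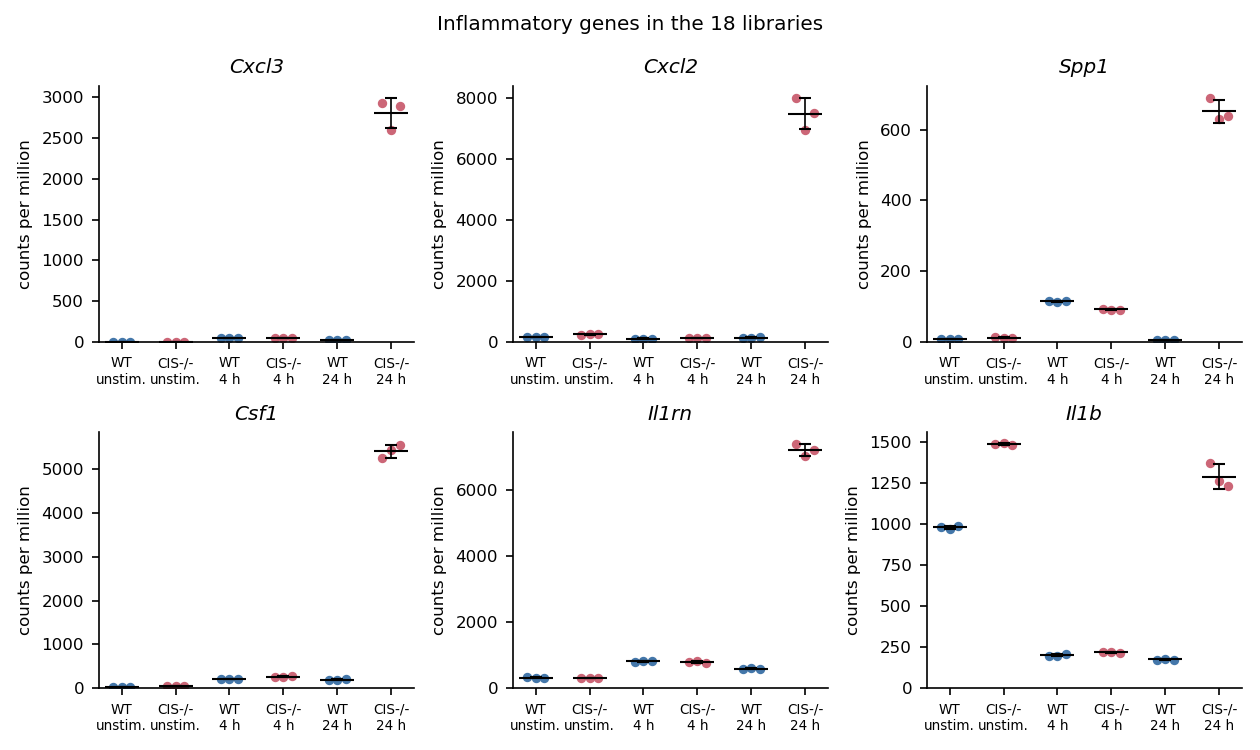
The CPM of 6 inflammatory genes in each library; points are libraries (blue WT, red labelled CIS-/-), and black lines mark the mean and SD of 3. Cxcl3, Cxcl2, Spp1, Csf1 and Il1rn were highest in the libraries labelled CIS-/- at 24 h, while Il1b was also high in unstimulated cells.

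Of 8827 genes called at 24 h, 4416 were higher and 4411 lower in the libraries labelled CIS-/-, and 3951 differed at least 2-fold. With library sizes alone 2558 were higher and 6999 lower, and the median of all genes was -0.552. Cytokines and chemokines were higher in 22 of 25 and lower in 2 (adjusted p = 1.74e-37). Immediate-early genes were higher in 24 of 26 and lower in 1 (adjusted p = 1.04e-17), Atf3 by 4.64 ± 0.04 and Dusp1 by 3.60 ± 0.03. Unfolded-protein and amino-acid stress genes were higher in 21 of 27 and lower in 3 (adjusted p = 3.72e-11), Ppp1r15a by 4.58 ± 0.06 and the chaperone gene Hspa5 by 2.16 ± 0.03. STAT5-associated genes were higher in 18 of 21 and lower in 2 (adjusted p = 2.35e-07), Dusp5 by 3.72 ± 0.04. In the MHC class II and costimulation list 11 of 14 were higher and 1 lower (adjusted p = 1.89e-06), led by Cd274, at 1510 ± 9.8 against 157 ± 3.4 CPM, Ctsl and Cd80. Migration and activation receptors were higher in 29 of 41 and lower in 10 (adjusted p = 4.18e-08), Cd14 by 3.88 ± 0.04 and Clec4e, a sensor of fungal and mycobacterial glycolipids, by 3.36 ± 0.04. Cholesterol genes were higher in 17 of 24 and lower in 3 (adjusted p = 0.000363).

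Anti-apoptotic genes were higher in 13 and lower in 3 of 16 at 24 h (adjusted p = 0.00242, and 0.0915 with an estimated correlation), Cflar by 1.93 ± 0.04, and monocyte and macrophage markers in 7 of 10 (adjusted p = 0.000397, and 0.0534 with an estimated correlation), Ctsb and Cd68 by 2.79 ± 0.03 and 2.71 ± 0.05. Stromal and endothelial markers were higher in 4 of 4 (adjusted p = 4.18e-08, a call lost with no low-count filter, adjusted p = 0.0558), with Pecam1, an adhesion molecule that leukocytes carry too, at 831 ± 16 against 53.2 ± 1.4 CPM, while Col1a2, Col3a1 and Sparc had 0 counts in these libraries. Erythroid markers were higher in 8 of 10 (adjusted p = 0.249), Hba-a1 at 7.85 ± 1.3 against 2.48 ± 0.36 CPM. Interferon-stimulated genes were split, 14 higher and 13 lower of 36 (adjusted p = 0.558), as were granule genes, 15 higher and 13 lower of 30 (adjusted p = 0.658), with Cd177 higher by 1.34 ± 0.03 and Lrg1 at -3.24 ± 0.06. The GM-CSF receptor and JAK-STAT list was split too, 15 and 13 of 30 (adjusted p = 0.527). Of its members, Csf2rb2 was higher by 1.28 ± 0.03 and Stat5b was at -1.46 ± 0.04. Ribosomal-protein genes took 0.577 ± 0.007% of the counts in WT and 0.263 ± 0.019% in libraries labelled CIS-/- at 24 h, against 0.418 ± 0.006% in unstimulated WT cells. Adjusted over the list alone, list counts changed by 1 gene at most, except for stem and progenitor genes, 5 in place of 3 lower, and cell cycle genes, 3 in place of 4 higher and 3 in place of 6 lower.

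**Figure D3:**
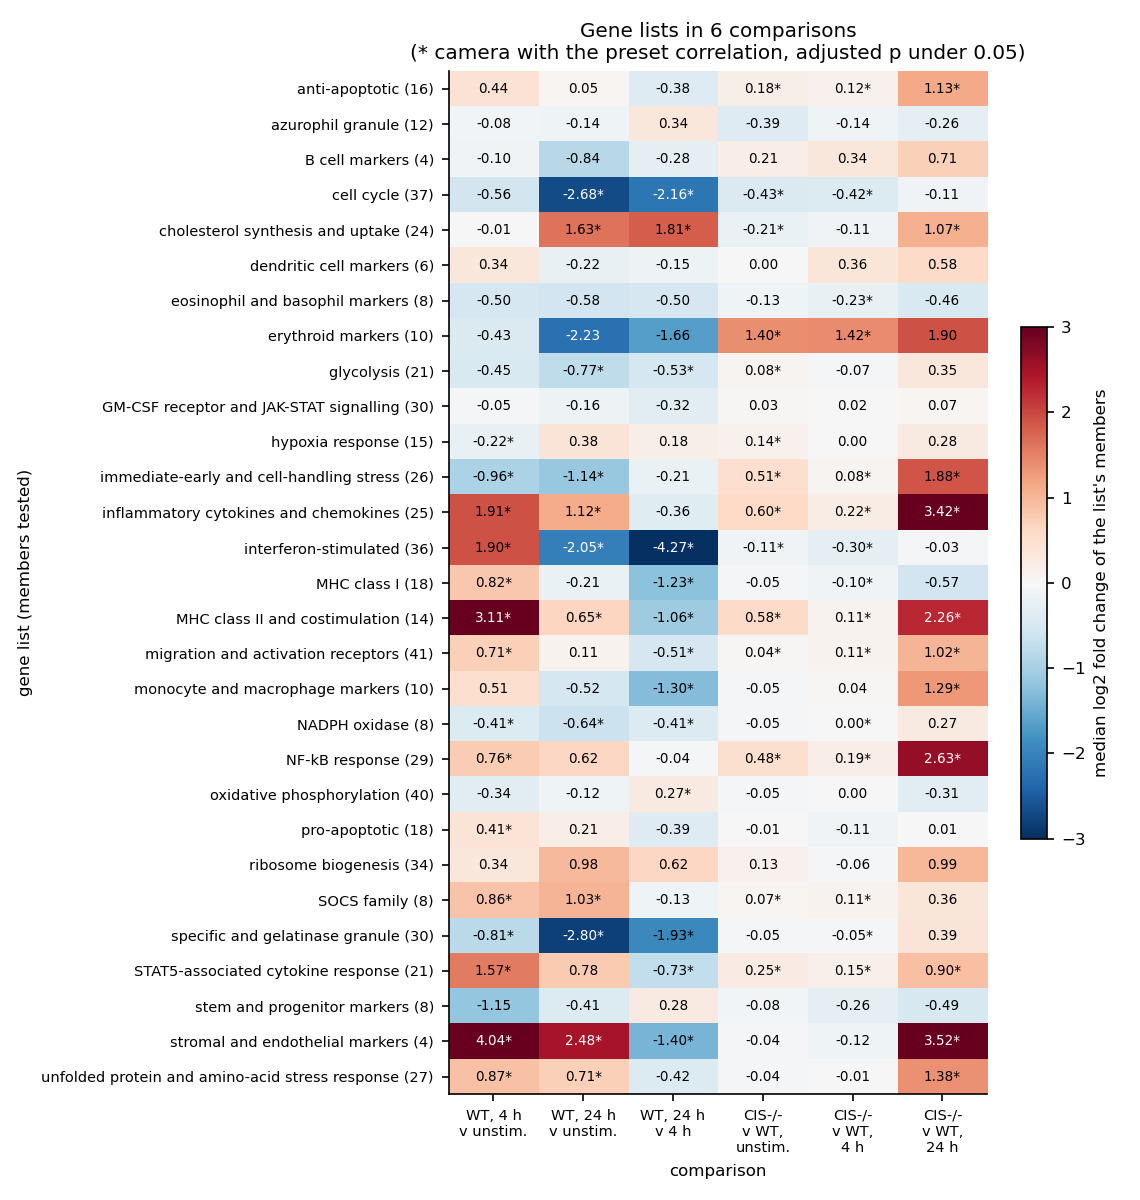
Median log2 fold change of the tested members of each gene list (number in brackets) in 6 comparisons, with an asterisk where camera with the preset correlation passed; colours stop at 3 in both directions, and the NADPH oxidase median at 24 h against 4 h turned its sign with library sizes alone. Interferon-stimulated genes stood at 1.90 in WT at 4 h and -2.05 at 24 h, and the cytokine list at 3.42 in libraries labelled CIS-/- against WT at 24 h.

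Whether the response itself differed by genotype was tested with interaction terms. At 4 h, 615 genes had a more positive and 1206 a more negative change in the cells labelled CIS-/-. The difference in log2 change was -3.78 ± 0.08 for Cish, -2 ± 0.10 for Ccl4 and -2.04 ± 0.07 for Zfand2a, a stress-induced gene. Immediate-early genes (18 of 26 more negative and 1 more positive, adjusted p = 2.51e-13), SOCS genes (3 of 8 more negative, Cish among them, adjusted p = 2.51e-13, and 0.00988 without Cish), NF-kB genes (15 of 29 more negative and 4 more positive, adjusted p = 1.37e-07), STAT5-associated genes (11 of 21 more negative and 2 more positive, adjusted p = 1.16e-06) and interferon-stimulated genes (19 of 36 more negative, adjusted p = 5.19e-07) were called. The starting level before GM-CSF, in libraries whose Cish goes against the label, was higher for these lists except the interferon one.

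At 24 h the interaction, which rests on the same unstimulated libraries, called 7489 genes, 3658 with a more positive and 3831 with a more negative change in cells labelled CIS-/-; with library sizes alone the split was 2028 and 6178, with a median of all genes of -0.51. The change was more positive for NF-kB genes in 27 of 29 (adjusted p = 8.46e-38), cytokines in 19 of 25 with 2 more negative (adjusted p = 1.03e-18) and unfolded-protein genes in 21 of 27 with 2 more negative (adjusted p = 9.53e-11). Spp1 differed by 6.38 ± 0.13, Csf1 by 4.19 ± 0.06, Il1rn by 3.61 ± 0.05 and Slc3a2, an amino-acid transporter gene, by 2.88 ± 0.06. Cd101 differed by -4.63 ± 0.05. Monocyte and macrophage markers had a more positive change in 6 of 10 (adjusted p = 1.22e-05).

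Averaged over the 3 conditions, the unstimulated one with its Cish against the label included, genes on chromosome 9, which holds Cish, stood out. Col6a4, a collagen gene, was higher by 5.93 ± 0.29, Ccrl2, an atypical chemoattractant receptor gene, by 3.38 ± 0.03 and Ccr3 by 3.15 ± 0.10, while Rpl29, a ribosomal protein gene, was at -2.42 ± 0.06 and Tma7 at -1.68 ± 0.06. In unstimulated cells Col6a4 stood at 32.7 ± 1.2 against 0.285 ± 0.11 CPM, and at 4 h it was 190 times as high (95% counting interval 64.6 to 923). Pcbp4, a gene of the same region named after its values were seen, had 0 counts in the libraries labelled CIS-/- at 4 h and 24 h and 21 and 32 counts in WT. The average called 7313 genes, 3530 higher and 3783 lower; with library sizes alone 1894 were higher and 6269 lower, with a median of -0.213. NF-kB genes were higher in 29 of 29 (adjusted p = 1.12e-77).

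**Figure D4:**
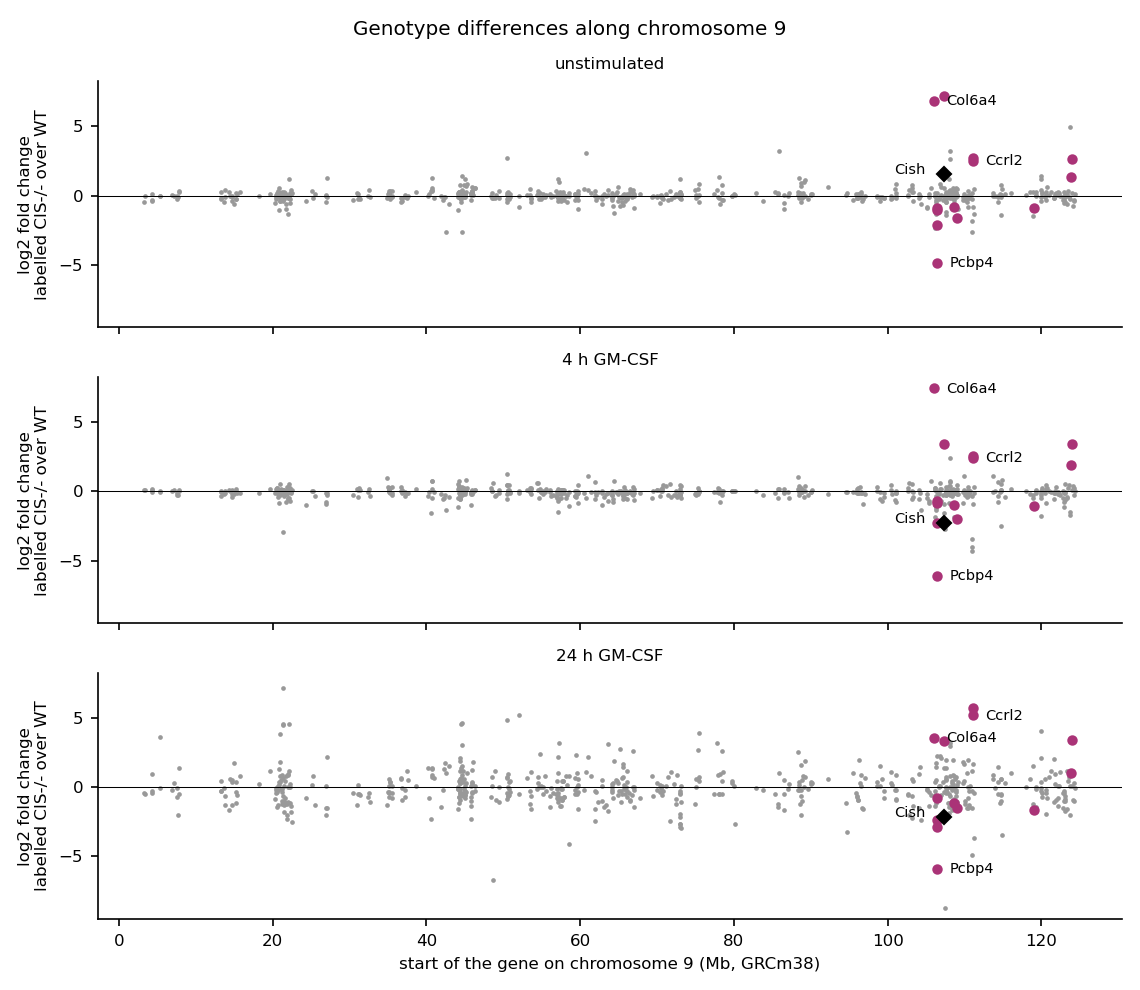
Log2 fold change of each tested gene on chromosome 9, libraries labelled CIS-/- over WT, against the start of the gene in Mb, for the 3 conditions; purple points passed at all 3 conditions with one sign and at least 1.5-fold, and the black diamond is Cish. The purple points lie in the part of the chromosome that holds Cish, with Col6a4 at 6.82 in unstimulated cells.

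Markers of other cells set the background of the sort. In WT cells at 4 h against unstimulated, monocyte and macrophage markers rose in 6 of 10 and fell in 3 (adjusted p = 0.344), dendritic cell markers split 3 and 3 of 6 (adjusted p = 0.767), B cell markers 1 and 1 of 4 (adjusted p = 0.835), and eosinophil and basophil markers fell in 3 of 8 (adjusted p = 0.3). Stem and progenitor markers rose in 2 and fell in 5 of 8 (adjusted p = 0.835), erythroid markers rose in 2 and fell in 5 of 10 (adjusted p = 0.765), and stromal and endothelial markers rose in 3 of 4 and fell in 1 (adjusted p = 2.15e-05, and 0.13 with no low-count filter), Pecam1 by 5.42 ± 0.05. Of the 20 T and NK cell markers 1 was tested, Cd3d, with a log2 fold change of -1.83 ± 0.19. At 24 h in WT cells erythroid markers fell in 8 and rose in 2 of 10 (adjusted p = 0.452), and stromal and endothelial markers rose in 3 and fell in 1 of 4 (adjusted p = 0.0337, and 0.0917 with an estimated correlation); Cd3d was at -4.32 ± 0.23. Against WT 4 h, WT 24 h stromal and endothelial markers fell in 4 of 4 (adjusted p = 0.00552, and 0.111 with no low-count filter), and monocyte and macrophage markers fell in 6 and rose in 2 of 10 (adjusted p = 0.0404, and 0.365 with an estimated correlation). At 24 h in cells labelled CIS-/- erythroid markers fell in 8 and rose in 2 of 10 (adjusted p = 0.649), stromal and endothelial markers rose in 4 of 4 (adjusted p = 2.22e-06, and 0.0555 with no low-count filter), and Cd3d was at -4.19 ± 0.27. Between genotypes in unstimulated cells, 1 monocyte and macrophage marker was higher and 1 lower of 10 (adjusted p = 0.502), and the B cell (adjusted p = 0.907) and stromal lists (adjusted p = 0.907) were not called.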

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

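The tests of monocyte transcripts, of handling, of the chromosome 9 window and of marker transcripts at 24 h were chosen after their results were seen, as were the splits of the libraries for WT at 4 h and for unstimulated libraries labelled CIS-/- against WT.

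The change with GM-CSF differed between genotypes by an interaction test: for 1821 genes at 4 h and 7489 genes at 24 h. Of 100 splits of the libraries drawn for the 24 h interaction, 1 called as many genes, the real one, and the highest other called 7236. For the 4 h interaction 2 of 100 splits called as many, the real one and a split that swapped the genotypes at one time and called 2695; the highest remaining called 838. Both shares lie under 0.05, but they do not decide whether the response differs by genotype. Of 200 possible splits 100 were drawn for each interaction. None of those drawn for 24 h swapped the genotypes at one time, as the 4 h split above the real one did. For the mean of the 3 conditions 1 of 100 splits, drawn from 4000 possible, called as many as the real 7313, and the highest other called 6774. Here too no split drawn swapped the genotypes at one time.

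For each comparison of 3 libraries with 3, 1 of 10 splits called as many genes, the real one, and 10 splits are too few for a share under 0.05. The highest other split called 1 gene for the 4 h genotype difference, where the real one called 2001. It called 0 genes in edgeR for the other comparisons: WT 4 h (8826), WT 24 h (9068), WT 24 h against 4 h (8714), libraries labelled CIS-/- at 4 h (8907) and 24 h (9727), unstimulated genotypes (2578) and genotypes at 24 h (8827).

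Genes that differed between genotypes at all 3 conditions, with one sign and at least 1.5-fold, gathered near Cish. In a window of 29 Mb around Cish on chromosome 9 there were 12 of 217 tested genes (5.53%), 5 higher and 7 lower, against 33 of 11352 elsewhere (0.291%), and at most 3 in another window of that length. With library sizes alone the share in the window was 25.3 times that elsewhere. A scaling factor shifts all genes of a library alike and cannot gather differences in 1 window, so this value is no test of scaling. An effect of losing CIS that is spread over the genome would not gather in 1 window. The 12 genes, against at most 3 in another window, argue against such an effect as their whole cause. DNA around the targeted gene that came from another strain, or was changed by the targeting, was not tested. For any single gene these explanations cannot be told apart. The window was set after the genes near Cish were seen, although the other windows of that length were counted too.

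NF-kB and immediate-early genes were higher in unstimulated libraries labelled CIS-/-, whose Cish goes against the label. For monocytes or macrophages in the sort, 8 of their abundant transcripts, among them C1qa, Mrc1, Ccr2 and Irf8, were picked after their counts were seen. They summed to 68 counts in the unstimulated libraries labelled CIS-/- and 113 counts in the WT ones. This gives no sign of more cells rich in these transcripts and decides nothing about other such cells. The fixed list of monocyte and macrophage markers had a median of -0.05, with Fn1 called higher and Ctsb lower, while the NF-kB list had a median of 0.48. Handling or time before lysis may contribute and cannot be told apart from genotype, because no label gives it. The 44 members called higher had a median of 0.59 unstimulated, 0.13 at 4 h and 2.3 at 24 h. A genotype difference in the animals stays open.

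At 24 h 3951 genes differed at least 2-fold between genotypes. With library sizes alone 79.5% of them (3142) kept call, direction and size. Leaving out the TMM factors moved the genes of this comparison down, so the 1848 lower ones were bound to keep direction and size. That share is thus no test of scaling. A shift alike for all genes cannot make 2103 genes 2-fold higher and 1848 lower, which argues against scaling as the whole cause. For monocytes, macrophages or stromal cells, 11 of their abundant transcripts, among them C1qa, Mrc1, Ccr2, Col1a2 and Sparc, were picked after their counts were seen. They summed to 37 counts in the libraries labelled CIS-/- and 87 counts in the WT libraries, which gives no sign of more cells rich in these transcripts. The fixed lists went the other way, with medians of 1.29 for monocyte and macrophage markers and 3.52 for stromal and endothelial markers. Other such cells are therefore not decided by this test. A longer culture of the cells labelled CIS-/- cannot be told apart from the genotype. Of 2594 genes 22.9% had the sign of the WT change from 4 h to 24 h, and of 2907 genes 62.5% had that of the WT change from unstimulated cells to 24 h. The planned bound of 60% on the first share decides nothing, because the WT 24 h libraries enter both of its sides with opposite signs and the second share goes the other way. A stronger or longer GM-CSF response without CIS may account for the difference, a hypothesis not tested here, since no library came from cells cultured without GM-CSF; a change of state within the neutrophils that raises Pecam1 and Col1a1 stays open too.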

How the results depend on the processing

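Library sizes without TMM factors, the genotype comparisons without a window of 29 Mb around Cish on chromosome 9, and the SOCS family without Cish were tests chosen after seeing the data; the others were planned. Of 202 counts of called genes under alternatives, 191 lay within 1.5 times the count reported. The others were those with an absolute log2 fold change of at least 1, which asks more of each gene: 4004 genes for WT at 4 h, 4004 for WT at 24 h, 3463 for WT 24 h against 4 h, 4202 for libraries labelled CIS-/- at 4 h and 5775 at 24 h, 202 between genotypes unstimulated, 126 at 4 h, 3951 at 24 h, 643 for their mean, 167 for the 4 h and 3501 for the 24 h interaction. With DESeq2 the counts ran from 1652 (4 h interaction) to 9520 (labelled CIS-/- at 24 h). Leaving out 1 library gave 2031 to 2141 genes between unstimulated genotypes, 1614 to 1779 at 4 h and 8476 to 8751 at 24 h. Without the chromosome 9 window these were 2493, 1907 and 8663. Whether the numbers of the replicates pair the libraries is not known. The labels do not say so, and 9 of 18 libraries were closest to those of their own number. A replicate block gave 2604 genes between unstimulated genotypes, 2024 at 4 h and 8839 at 24 h.

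Of 23739 values for named genes, 23554 counted as unchanged: called values that kept call and direction, and values not called that stayed so, whatever their sign. A missing adjusted p also counted as unchanged. Of the others, 105 lost and 70 gained a call, 8 called values turned their sign and 2 turned and gained a call, these 10 with library sizes alone. Against WT 4 h, WT 24 h Cish became 0.37 and Hexa 0.06. Between genotypes at 24 h Runx2 became -0.22, Ncf4 -0.01 and Socs4 -0.09; Socs4 became -0.01 for the mean, and in the 24 h interaction Runx2 became -0.29 and Socs4 -0.06. Between genotypes at 24 h the median of all genes was -0.55 with library sizes alone and -0.02 with TMM factors. Of 5463 list results, 5185 were unchanged by the same rule, 153 lost and 121 gained a call, and in 4 camera gave the other direction. These were the SOCS family between genotypes at 4 h, whose median was 0.11 as reported, 0.12 with no low-count filter (adjusted p = 0.574), 0.11 with a replicate block (adjusted p = 0.865), 0.09 with limma-voom (adjusted p = 0.697) and 0.12 without Cish (adjusted p = 0.000758), so Cish carried the direction reported. Medians of called lists crossed 0 without a turn by camera for MHC class II in WT at 24 h (-0.13 without WT unstimulated replicate 1) and NADPH oxidase in WT 24 h against 4 h (0.07 with library sizes alone). So did that of eosinophil and basophil markers between genotypes at 4 h (0.07 without WT 4 h replicate 2, 0.1 without replicate 3 and 0.01 with no low-count filter). With an estimated correlation 61 of 319 list results lost their call. With 200 changed genes, the simulated unstimulated genotype comparison recovered 44% of the smallest changes. It called 148 genes where the real comparison called 2578, so its adjusted threshold was stricter. That share therefore does not carry over to the real comparison.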

Other observations

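Ribosomal-protein genes, the share of the 10 highest genes and the top gene differed between groups. The 10 highest genes took 14.9% of the counts in unstimulated WT libraries, 9.82% at 4 h and 7.98% at 24 h, and 13.9, 9.83 and 11.5% in the libraries labelled CIS-/-. The top gene was S100a9 in unstimulated WT libraries (4.154 ± 0.083% of counts, SD of 3) and Fth1 in libraries labelled CIS-/- at 24 h (2.98 ± 0.202%). Mitochondrial genes took 0.147 to 0.248% of the counts of a library.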
